A study of Mus musculus with 4 samples.

How the data were processed

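RNA was measured in dendritic cells sorted from spleens of C57BL/6 mice 12 days after injection of recombinant Flt3L, in 4 samples: 2 of conventional dendritic cells (cDC) and 2 of plasmacytoid dendritic cells (pDC). Per the labels' protocols, 1 µg of total RNA per sample was labelled with biotin, and the cells were enriched with magnetic beads (against CD11c for cDC and PDCA-1 for pDC) before a flow sort on CD11c and B220. Groups and replicate numbers were taken from the sample titles. The free-text descriptions name lung where titles and protocols name spleen, and this conflict was left as it stands. Nothing in the labels says that the 2 samples of a cell type came from separate mice, so the p-values measure only the spread between these samples, which may be technical. No pair of arrays held identical values.

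The deposited table holds 1 intensity per probe set and array, and per the submitters' processing notes RMA and the affy package were used, without versions (not given in the sources used here). Their order, parameters and the chip description used are not given either. The values are positive, from 4.97 to 22280.3, and have array medians of 13.0 to 13.6, so they lie on a linear scale rather than the log2 scale that RMA gives. The plan allowed for this, and log2 was taken first. No detection calls were used here, so a level near the array median or near the 6.94 to 9.04 of the bacterial tryptophan-gene control probe sets has no firm meaning as present or absent. Background, normalisation and summary steps of this kind compress differences at the dim end, so folds against a dim group are limited there. Signal intensity differs between probe sets for reasons of sequence, so levels of different probe sets, where given side by side, do not rank their transcripts. Scan dates were not used here. As for any arrays, their number limits the precision: 2 arrays per cell type leave 2 residual degrees of freedom, and an exact permutation of 2 against 2 cannot give a two-sided p below 0.333.

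Of 45101 probe sets, 64 controls were left out and 45037 were tested. Probe sets were named from the platform annotation that pairs them with genes: 34945 had 1 gene symbol, 932 had several and 9160 were unnamed here. Symbols were checked by Entrez identifier against a RefSeq gene table (assembly GRCm38.p6), where 34741 were found and 0 changed, and no coordinates were used. This gave 18193 genes, each represented by the probe set with the highest mean over the 4 arrays. Of 9010 genes with more than 1 probe set, 8 had probe sets called in opposite directions.

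The comparison of pDC with cDC was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on all 4 arrays with the group as the only term, two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. The prior had 3.38 degrees of freedom and a variance of 0.0212. Gene lists were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the 35 lists with 5 or more measured genes, of which 12 passed, 5 as higher and 7 as lower in pDC. With the correlation estimated from these arrays 0 of the 35 passed in camera, 7 had an unadjusted p under 0.05, and the lowest adjusted p was 0.206. The estimate was 0.0108 for conventional dendritic cell markers, -0.0471 for cDC1 markers and 0.721 for interferon-stimulated genes. For the conventional and cDC1 lists it lay near or below the preset 0.01. A higher correlation between genes therefore does not account for their lost calls. With fry of limma, which asks whether a list's genes move one way on balance and does not compare them with other genes, 17 passed. The lists of dendritic cell subsets, MAPK signalling, immune functions, housekeeping processes and other cell types were fixed from general knowledge before the data were examined. They hold 726 distinct names, of which 5 were matched through a synonym and 80 had no probe set of a single gene. Lists overlap, and the counts adjusted over a list alone use the same p-values within that list. Figures were drawn with matplotlib 3.10.9.

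The genes named were set by a rule fixed before the data were examined: all MAPK phosphatases; Itgax, Ptprc and Bst2 as checks of the sort; the 12 genes with the largest fold in each direction among those called whose arrays did not overlap between cell types, leaving out antigen receptor segments; up to 4 members with the largest difference from each other list; and Siglech, Tcf4, Irf8, Tlr7, Tlr9, Zbtb46, Id2, Irf4, Xcr1 and Sirpa. It gave 155 genes, of which 120 were called, 60 in each direction. Genes outside it were chosen after their values were seen: Adgre1, Ccl4, Cd200, Cd3d, Cd3e, Cd3g, Cd68, Clec10a, Csf2rb, Ebf1, Epcam, Fcgr1, Fos, Hmox1, Ifna2, Ifna4, Ifnb1, Il12a, Il3ra, Irf7, Jchain, Jun, Kmo, Pax5, Prdm1, Rag1, Sdf2l1, Sftpc, Tyms and Vcam1. The genes next in size of difference given under the other observations (Adam8, Asb2, Capg, Cbr3, Cdca8, Chdh, Cox6a2, Fgl2, Havcr1, Mctp2, Pclaf, Pgam2, Rasgrp3, Sh3bgr, Slc49a4, Sult1a1, Timp2 and Upb1) were chosen in that way too.

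The fit was tested on simulated data with the real probe sets' means and a spread drawn from the fitted model, in 5 simulations each, with the changed probe sets taken from those brighter than the median. With 200 of 45037 probe sets changed, it recovered 0% of those changed 1.5-fold or 2-fold and 76.7% of those changed 4-fold, and 4.17% of calls were false. With 6000 changed, nearer to the number called here, it recovered 87.8% at 2-fold, 98.7% at 4-fold and 99.8% at 16-fold, with 4.29% of calls false. The noise came from the model that was then fitted, so the share of false calls was set in advance and does not check these arrays. In the runs with 200 probe sets changed, camera called a list of 20 genes raised 2-fold in 5 of 5 simulations and 0 of 100 unchanged lists. With an estimated correlation it called the raised list in 0 of 5. Few other genes differed in those runs, against 3335 of 18193 called here. Camera compares a list with the other genes, so the 5 of 5 may overstate its power here. The simulated genes were drawn independently of each other. The 0 of 100 therefore does not bear on lists whose genes vary together.

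Alternatives planned before the data were examined were quantile normalisation, median centring, a filter on dim probe sets, eBayes with an intensity trend (also robust), array weights, the replicate number as a block, leaving out each array in turn, stricter thresholds, other ways to represent a gene, camera with an estimated correlation and fry. A floor at each array's median was added after seeing the data.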

Results

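Gene expression was measured in 2 kinds of dendritic cell sorted from the spleens of C57BL/6 mice, the plasmacytoid dendritic cell (pDC), known as a major source of type I interferon, and the conventional dendritic cell (cDC), known for presenting antigen to T cells. The mice had been given recombinant Flt3L, a cytokine that expands dendritic cells, and the spleens were taken 12 days later. The pDC were enriched with beads against PDCA-1 (the product of Bst2) and the cDC with beads against CD11c (the product of Itgax), and both were then sorted by their CD11c and B220 stain. The beads thus differed with the cell type, so an effect of the isolation on any gene cannot be told apart from one of cell type. Each cell type was hybridised to 2 Affymetrix arrays, 1 per sample, with 1 µg of total RNA for each, so that the number of arrays limits the precision of every value given here. The title and the protocol of each sample name spleen, whereas its free-text description names lung, and the samples were taken as splenic.

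The 4 arrays held similar ranges of intensity, with medians on the log2 scale of 3.77 and 3.73 on the cDC arrays and 3.69 and 3.73 on the pDC arrays. Across probe sets, which are not independent replicates, the log2 intensities correlated at r = 0.990 between the cDC arrays, at r = 0.991 between the pDC arrays and at 0.926 to 0.930 between arrays of different cell type. The series title names Dusp9, which encodes a dual-specificity phosphatase that inactivates mitogen-activated protein kinases (MAPK), and the comparison of pDC with cDC asks how its transcript and those of other genes differ between the cell types. Differences below are log2 values of pDC minus cDC, each gene is represented by its brightest probe set, and a gene is called when its adjusted p in limma was under 0.05. Most genes are named by a rule fixed before the data were examined, and those chosen after their values were seen are listed with the processing.

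Dusp9 was higher in pDC than in cDC on all 3 of its probe sets. The brightest of them, of the kind with the suffix _a_at, measured 201 ± 40.3 (SD, n = 2) in pDC against 36.9 ± 3.77 in cDC, a 5.40-fold difference (log2 2.43, SE 0.18, adjusted p = 0.00111 in limma). On the probe set with the plain suffix _at it measured 235 ± 116 against 11.0 ± 0.332, which is 20.1-fold (adjusted p = 0.00133), and on the one with the suffix _x_at 260 ± 105 against 9.89 ± 0.983, which is 25.2-fold (adjusted p = 0.00061). The cDC values on these latter probe sets lay close to the 6.94 to 9.04 of the bacterial tryptophan-gene control probe sets across the arrays, and the suffix _x_at marks probes that can hybridise to other transcripts. Both pDC arrays were above both cDC arrays on every Dusp9 probe set.

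No other member of the MAPK phosphatase family was called higher in pDC. Of the 10 measured, Dusp9 was called higher in pDC, 4 were called lower and 5 were not called, and the counts were the same when adjusted over the list alone. The lower ones were Dusp2 (log2 -4.58, adjusted p = 0.00237), an immediate-early nuclear phosphatase, Dusp1 (-2.87, adjusted p = 0.00308), Dusp16 (-1.57, adjusted p = 0.0014) and Dusp6 (-1.53, adjusted p = 0.0129), a cytoplasmic phosphatase of ERK. For Dusp16, 1 of 2 probe sets was called, and the other differed by -0.33. In cDC, Dusp1 reached 8988 ± 2410 (SD, n = 2), against 1238 ± 407 in pDC. Dusp7 (0.27, adjusted p = 0.339) and Dusp4 (-0.36, adjusted p = 0.26) were not called, although the arrays of the cell types did not overlap. For Dusp5 (-0.02), Dusp8 (-0.23) and Dusp10 (-0.17) they overlapped. As a list the family did not pass camera (adjusted p = 0.142, median -0.29), although without cDC replicate 1 it did (adjusted p = 0.0425). The median was -0.62 without cDC replicate 1 and -0.75 without pDC replicate 2. Dusp6 lost its call without cDC replicate 2 (adjusted p = 0.052).

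**Figure D1:**
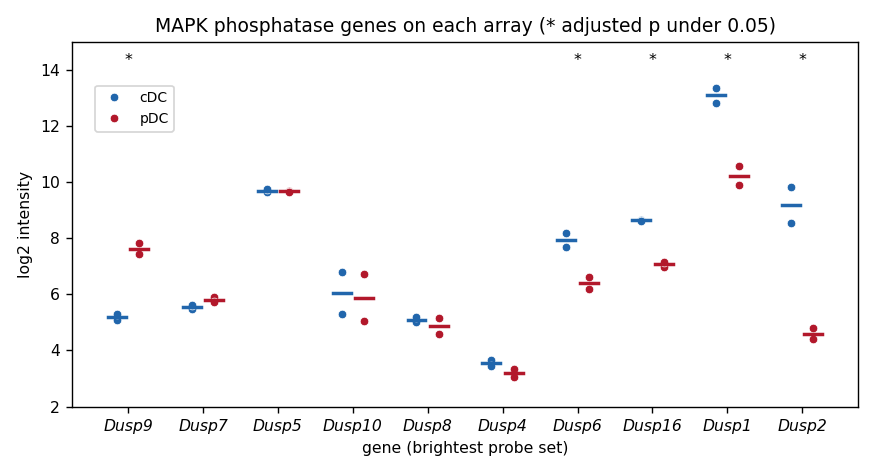
Log2 intensity (vertical axis) of the brightest probe set of each of the 10 MAPK phosphatase genes (horizontal axis), with 1 point per array, blue for cDC and red for pDC, and a bar at each group's mean; an asterisk marks genes called by limma. Dusp9 lies higher on both pDC arrays (log2 difference 2.43), and Dusp6, Dusp16, Dusp1 and Dusp2 lie lower on both.

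The remaining signalling genes around MAPK moved in a mixed way, and some immediate-early genes were lower in pDC. Of 28 immediate-early genes and ERK targets, 12 were called lower in pDC and 16 were not called (13 lower when adjusted over the list alone), with the largest differences in the nuclear receptors Nr4a2 (-7.01) and Nr4a3 (-5.12) and in the zinc finger factors Egr3 (-5.58) and Egr2 (-5.06). Their probe sets differed, with 4 of 6 called for Nr4a2, 1 of 3 for Nr4a3, 1 of 2 for Egr3 (the other at -0.12) and 2 of 2 for Egr2. Fos and Jun, which are in the same list, differed by -0.57 (adjusted p = 0.208) and 0.18 (adjusted p = 0.892) and were not called. Because the beads differed, an effect of the isolation on immediate-early genes cannot be told apart from one of cell type. The list passed camera as lower in pDC (median -0.77, adjusted p = 6.92e-06), but not camera with an estimated correlation (adjusted p = 0.36). Without cDC replicate 2 or pDC replicate 2, 1 member was called higher. Among 31 MAPK cascade kinases, 4 were called higher, 4 lower and 23 were not called (6 and 8 when adjusted over the list alone, camera adjusted p = 0.439), with Mapkapk3, which encodes a kinase activated by p38, at -1.04 and Araf at 1.19, the latter not called without cDC replicate 1 (adjusted p = 0.0538). The higher kinases numbered 2 without cDC replicate 1 or pDC replicate 2, and the lower ones 1 without cDC replicate 2 or pDC replicate 1. Of 16 atypical dual-specificity phosphatases, Dusp3 (-1.76) and Styx (-0.74) were called lower and 14 were not called (1 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.798). The call of Styx was lost when any array was left out (adjusted p from 0.0623 without cDC replicate 2 to 0.132 without cDC replicate 1), and that of Dusp3 without cDC replicate 2, pDC replicate 1 or pDC replicate 2 (adjusted p = 0.0652, 0.159 and 0.0841). Dusp28 was called higher without cDC replicate 1 (1.57, adjusted p = 0.0144).

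Across the genome, the cell types differed in 6013 of 45037 probe sets (13.4%), of which 3364 were higher and 2649 lower in pDC. By gene, 1814 were higher and 1521 lower among 18193, and 24 genes were at least 64-fold higher in pDC and 14 at least 64-fold lower. The arrays of the cell types did not overlap for 56.2% of genes, against 33.3% by chance. Led by Klk1, a tissue kallikrein, the genes most raised in pDC were Klk1 (log2 9.85, 922-fold), D13Ertd608e (9.37), Siglech (8.29, 313-fold), which encodes a sialic acid-binding lectin of pDC, Klk1b27 (8.13), Ly6d (7.98), Smim5 (7.93), the cysteine protease gene Ctsl (7.65), Cd8b1 (7.61), Atp1b1 (7.57), Slco4a1 (7.46), Hsd11b1 (7.20) and Mzb1 (7.13). Klk1 and Klk1b27 are close paralogs, so that the share of each in these signals is uncertain. Those most raised in cDC were the chemokine gene Cxcl9 (-8.35, 327-fold), Tgfbi (-7.38), Anxa1 (-7.09), Tlr3 (-7.03), which encodes a receptor for double-stranded RNA, Nr4a2 (-7.01), Il1b (-6.94), Naaa (-6.72), Ctla2b (-6.68), Gcsam (-6.57), Slamf8 (-6.51), Batf3 (-6.44), which encodes a transcription factor of cDC1, and Ptgs2 (-6.21). All of these had adjusted p between 5.14e-05 and 0.000398, and in the cell type where they were lower their mean intensities were 7.57 to 52.4, close to the array medians for most, so that their folds are limited by the dim end of the arrays. The count of higher probe sets fell to 1972 without cDC replicate 1 and that of lower ones to 1694 without pDC replicate 2.

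**Figure D2:**
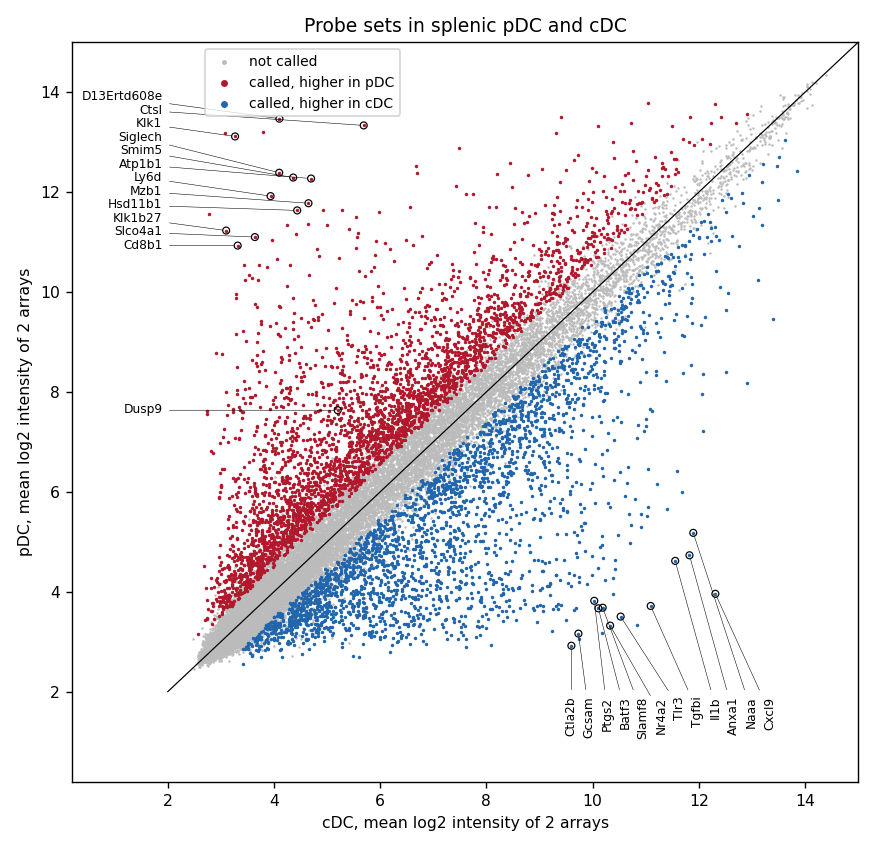
Mean log2 intensity of the 2 cDC arrays (horizontal axis) against that of the 2 pDC arrays (vertical axis), with 1 point per probe set, red for those called higher in pDC, blue for those called higher in cDC and grey for those not called. The 12 named genes with the largest folds in each direction and Dusp9 are circled; Klk1 and Siglech lie far above the line of equal intensity and Cxcl9 far below it.

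The sort markers, given as checks, differed unequally. Bst2 was higher in pDC by 4.14 (adjusted p = 0.000189). Itgax did not pass the test (-0.62, adjusted p = 0.425). Ptprc, whose longer isoforms carry the B220 epitope, differed by 0.12 on its brightest probe set (adjusted p = 0.695) and by 1.32 on its other probe set (adjusted p = 0.0284).

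Genes that identify the dendritic cell subsets separated the arrays. Of 25 pDC markers, 22 were called higher in pDC (24 when adjusted over the list alone), among them Ly6d and Siglech, the transcription factor genes Spib (6.05) and Tcf4 (4.34), the latter encoding the E protein that specifies pDC, and Tlr7 (3.50). Tlr9, Il3ra and Irf7 were not called, at 0.25, 0.51 and 0.91, and the single Tlr9 probe set measured 38.8 ± 0.516 in pDC against 32.7 ± 1.77 in cDC (SD, n = 2). The list passed camera (median 4.77, adjusted p = 1.7e-26; adjusted p = 0.206 with an estimated correlation). Of 25 conventional dendritic cell markers, 16 were called lower in pDC, 3 higher and 6 were not called (19 and 3 when adjusted over the list alone), with Id2, an inhibitor of E proteins, at -5.75 and Zbtb46 at -3.66. The 3 higher ones were the lectin gene Clec10a (5.62), the kynurenine enzyme gene Kmo (2.28) and the cytokine receptor gene Csf2rb (0.89). This list also passed (median -2.25, adjusted p = 6.39e-10; adjusted p = 0.206 with an estimated correlation).

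Within the conventional lineage, the markers of cDC1, the cross-presenting subset, were lower in pDC almost throughout, and those of cDC2 went both ways. All 18 measured cDC1 markers were called, 17 lower in pDC and Irf8 higher, with the same counts when adjusted over the list alone. They included the chemokine receptor gene Xcr1 (-5.44), Batf3 and Tlr3, and the list passed camera (median -4.17, adjusted p = 1.34e-17; adjusted p = 0.206 with an estimated correlation). Irf8, a transcription factor gene used by both pDC and cDC1, was bright in both cell types and higher in pDC by 0.66 (adjusted p = 0.0452), a call that was lost when any array was left out (adjusted p from 0.0623 without pDC replicate 1 to 0.192 without cDC replicate 1). Of 19 cDC2 markers, 6 were called higher, 9 lower and 4 were not called, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.277). Without pDC replicate 1 the lower ones numbered 5. Cd7 (3.64), Cd4 (2.82), Sirpa (1.63) and Irf4 (1.15, the other probe set at 0.57 and not called) were higher in pDC, and Il1r2 (-4.34) and S100a4 (-4.17) were lower. Of 35 dendritic cell transcription factors, 10 were called higher, 12 lower and 13 were not called (13 and 13 when adjusted over the list alone), from Spib (6.05) to Batf3 (-6.44). That list did not pass (adjusted p = 0.798), and its median (0.06) was positive where its mean (-0.12) and its test were negative. The median was 0.17 without cDC replicate 1, and it turned negative without cDC replicate 2 (-0.11) or pDC replicate 2 (-0.28).

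Most costimulatory genes were lower in pDC, and cytokine genes went both ways. Of 25 genes of costimulation and maturation, 18 were called lower in pDC, 1 higher and 6 were not called (21 lower and 1 higher when adjusted over the list alone), among them Cd83 (-4.74), the actin-bundling gene Fscn1 (-4.19), Marcksl1 (-5.30) and the chemokine gene Ccl5 (-5.60). Cd200, which encodes an inhibitory ligand, was the higher one (2.68). For Fscn1, 1 of 4 probe sets was called, and the weakest differed by -0.08. The list passed camera (median -1.89, adjusted p = 3.93e-12; adjusted p = 0.206 with an estimated correlation). Of 25 cytokine genes, 10 were called lower, 2 higher and 13 were not called, also when adjusted over the list alone (camera adjusted p = 0.000179, median -0.29; adjusted p = 0.226 with an estimated correlation). Besides Cxcl9, Il1b and Ccl5, Il12b (-4.74), which encodes a subunit of interleukin-12, was lower in pDC, whereas Ccl4 (2.18) and Il12a (0.70) were higher. Without cDC replicate 1 or pDC replicate 2, 1 cytokine gene was higher. The interferon genes Ifnb1, Ifna2 and Ifna4 lay between 3.4 and 3.7 on the log2 scale in both cell types and were not called.

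Some interferon-stimulated genes were lower in pDC, and the list differed between the cDC arrays. Of 29 measured, 7 were called lower, Bst2 higher and 21 were not called (13 and 3 when adjusted over the list alone), with Cxcl10 (-3.98), Rtp4 (-3.59) and Ifit3 (-3.47) the most reduced. For Rtp4, 1 of 2 probe sets was called, and the other differed by -0.56. The list passed camera (median -0.93, adjusted p = 0.012; adjusted p = 0.769 with an estimated correlation, 0.345 in fry and 0.139 with a floor at each array's median). It did not pass without cDC replicate 1 (adjusted p = 0.0791), where 28 of the 29 genes were higher than on cDC replicate 2, by a median of 1.11. Between the pDC arrays 14 of the 29 were higher on replicate 1 and the median difference was -0.0502. Without cDC replicate 2, 18 genes were called lower and the median was -1.37. Without cDC replicate 1, 2 were called higher and the median was -0.39.

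**Figure D3:**
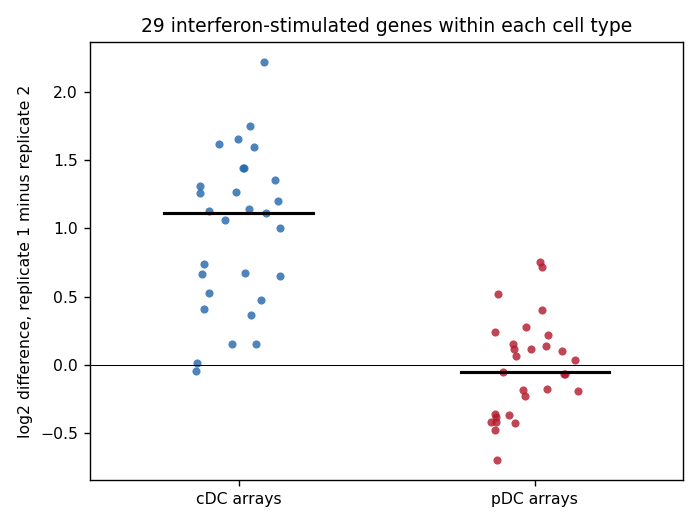
Log2 difference of replicate 1 minus replicate 2 (vertical axis) for each of the 29 interferon-stimulated genes within the cDC arrays (blue) and within the pDC arrays (red), with a bar at each median. The cDC points centre on 1.11 and the pDC points on -0.0502.

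Sensing and antigen presentation genes went in both directions. Of 27 Toll-like receptor and adaptor genes, 4 were called higher, 5 lower and 18 were not called (7 and 11 when adjusted over the list alone, camera adjusted p = 0.399), with Tlr7, a sensor of single-stranded RNA, higher and Tlr3, Tlr13 (-4.02) and Tlr1 (-2.67) lower in pDC. The higher ones numbered 2 without cDC replicate 1 or pDC replicate 1. Of 15 genes of MHC class II presentation, 3 were called higher, 6 lower and 6 were not called (4 and 7 when adjusted over the list alone, camera adjusted p = 0.322). Ctsl was higher, and H2-Ob (-4.45), Marchf1 (-2.24) and the transactivator gene Ciita (-2.51) were lower, the last of these not called without cDC replicate 1 (adjusted p = 0.123) or pDC replicate 2 (adjusted p = 0.07). The lower ones of this list numbered 3 without cDC replicate 1 or cDC replicate 2 and 2 without pDC replicate 2. Of 18 genes of MHC class I presentation, 3 were higher, 3 lower and 12 were not called (5 and 5 when adjusted over the list alone, camera adjusted p = 0.856). Cybb, which encodes a subunit of the phagocyte oxidase, was higher (3.56) and Wdfy4 lower (-3.32, with 1 of 2 probe sets called and the other at -0.59). When any array was left out 1 gene was called higher, and without cDC replicate 1 or pDC replicate 2 also 1 lower.

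Receptor genes also divided. Of 26 cytokine and growth factor receptor genes, 10 were called higher, 4 lower and 12 were not called (12 and 7 when adjusted over the list alone, camera adjusted p = 0.277), with Il7r (5.85), Lifr (4.77) and Csf2rb2 (3.59) higher and the stem cell factor receptor gene Kit (-4.01) lower in pDC. The median of this list (-0.0463) was negative where its mean (0.51) and its test were positive, but it was positive without cDC replicate 1 (0.18) or pDC replicate 1 (0.021). Of 24 chemokine receptor and adhesion genes, 7 were higher, 4 lower and 13 were not called (9 and 5 when adjusted over the list alone, camera adjusted p = 0.49). The gut-homing receptor gene Ccr9 (5.15) and S1pr4 (4.14) were higher, and Xcr1 and the integrin gene Itgae (-3.90) were lower. Of 24 genes of TGF-beta and SMAD signalling, 4 were higher, 2 lower and 18 were not called (4 and 6 when adjusted over the list alone, camera adjusted p = 0.856), with the receptor gene Tgfbr1 at 2.80 (1 of 3 probe sets called, the weakest at 0.35) and Id2 at -5.75. Without cDC replicate 1, 1 was higher, and without cDC replicate 2, pDC replicate 1 or pDC replicate 2, 1 was lower.

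More genes of the secretory pathway were called higher than lower in pDC, and nearly all cell cycle genes were lower. Of 34 genes of the unfolded protein response and secretory pathway, 17 were called higher, Sdf2l1 lower (-1.29) and 16 were not called (21 and 2 when adjusted over the list alone), with Edem2 (2.58) and Xbp1 (2.33), a transcription factor gene of secretory cells, the most raised. For Edem2, 1 of 2 probe sets was called (the other at 0.20), and for Xbp1 3 of 4 were. The list passed camera (median 0.71, adjusted p = 5.62e-07; adjusted p = 0.54 with an estimated correlation). The higher ones numbered 8, 6 and 7 without cDC replicate 1, pDC replicate 1 and pDC replicate 2, and Sdf2l1 lost its call without pDC replicate 1 or pDC replicate 2. Of 29 cell cycle genes, 28 were called lower in pDC, also when adjusted over the list alone, and Tyms, near the dim end on every array, was not (0.07). Rrm2 (-6.02), Mki67 (-5.80), Top2a (-5.36) and Cdk1 (-5.35) differed most (camera adjusted p = 1.7e-26, median -3.22; adjusted p = 0.206 with an estimated correlation). Mki67 measured 25.3 ± 7.02 in pDC and 1398 ± 355 in cDC (SD, n = 2). Of 29 cytoplasmic ribosomal protein genes 2 were higher, 1 was lower and 26 were not called (2 higher when adjusted over the list alone, camera adjusted p = 0.542). Both higher calls were lost without cDC replicate 1 or pDC replicate 2 and 1 of them without cDC replicate 2 or pDC replicate 1. The lower call was lost without cDC replicate 2, pDC replicate 1 or pDC replicate 2. Of 38 oxidative phosphorylation genes Ndufs3 (0.72) was higher and 37 were not called. That last call was lost when any array was left out (adjusted p from 0.0623 without cDC replicate 2 to 0.0981 without cDC replicate 1) and when adjusted over the list alone, and the list did not pass (adjusted p = 0.475). Without pDC replicate 1, 2 of its genes were called lower.

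**Figure D4:**
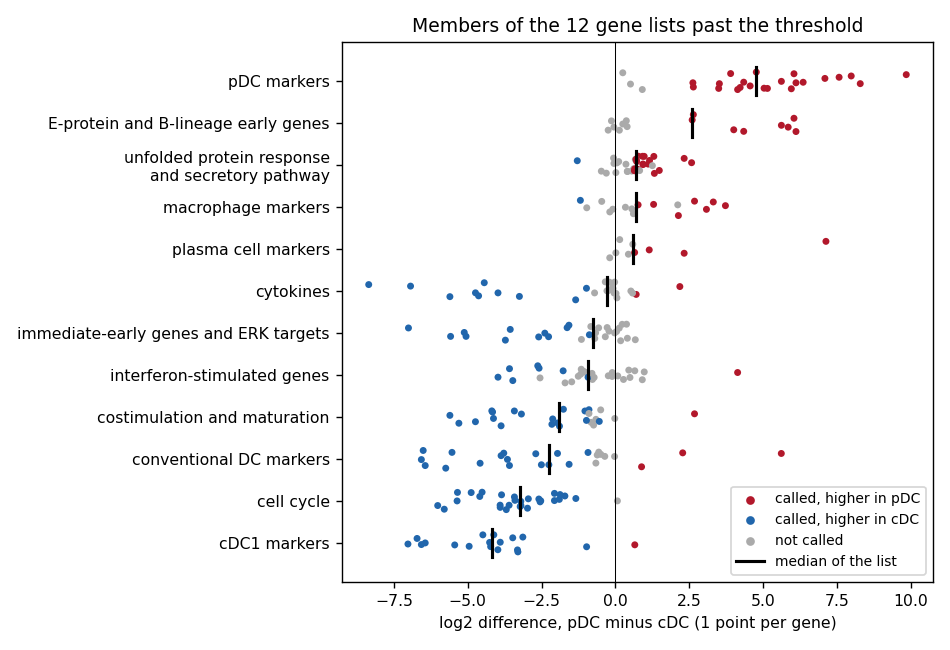
Log2 difference of pDC minus cDC (horizontal axis) for each measured member of the 12 gene lists that passed camera (vertical axis), with 1 point per gene, red for those called higher in pDC, blue for those called higher in cDC and grey for those not called, and a black bar at each list's median. The medians run from -4.17 for cDC1 markers to 4.77 for pDC markers.

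Several genes best known from lymphocytes were higher in pDC. Of 15 genes of the E-protein and early B lineage list, 8 were called higher and 7 were not called (9 higher when adjusted over the list alone; median 2.60, camera adjusted p = 2.99e-07). This call too was lost in camera with an estimated correlation (adjusted p = 0.213), and 5 of the 15 are also in the pDC marker list. Blnk (6.11), Dntt (5.62), which encodes terminal transferase, and Cd79b (4.01) were higher, whereas Ebf1 and Rag1 were not called and lay near the dim end of the arrays. Of 9 plasma cell markers, Mzb1, Xbp1, Irf4 and Sdc1 (0.65) were called higher and 5 were not called (6 higher when adjusted over the list alone; median 0.59, camera adjusted p = 0.00126; adjusted p = 0.287 with an estimated correlation). Prdm1 and Jchain, which mark antibody-secreting cells, differed by -0.19 and 0.44 and were not called, and the call of Sdc1 was lost when any array was left out (adjusted p from 0.0597 without pDC replicate 1 to 0.162 without cDC replicate 1). Of 14 B cell markers 5 were called higher, 2 lower and 7 were not called, also when adjusted over the list alone (camera adjusted p = 0.419), with Cd79b and Fcrla (3.70) higher, Ms4a1 (-3.03) and Cd22 (-2.76, the other probe set at -0.43 and not called) lower, and the B lineage factor gene Pax5 at -0.01. Without cDC replicate 1, cDC replicate 2 or pDC replicate 2, 3 B cell markers were higher. Of 15 T cell markers 4 were higher (Il7r, Cd28 at 3.13, Cd2 at 1.95 and Lat at 1.71) and 11 were not called, also when adjusted over the list alone. The calls of Cd2 and Lat were lost without cDC replicate 2 (adjusted p = 0.112 and 0.0832), as was that of Cd2 without cDC replicate 1 (adjusted p = 0.101). The CD3 chain genes Cd3d, Cd3e and Cd3g lay between 3.4 and 4.8 on the log2 scale in both cell types. The T cell list did not pass (adjusted p = 0.173) but did without pDC replicate 1 (adjusted p = 0.0346). For both lists the median (-0.03 for B cells and -0.00476 for T cells) was negative where the mean (0.40 and 0.83) and the test were positive. These signs rest on single arrays. The B cell median was positive without cDC replicate 1 (0.0645), cDC replicate 2 (0.00379) or pDC replicate 1 (0.0216), and that of T cells without cDC replicate 1 (0.0861), cDC replicate 2 (0.0318) or pDC replicate 2 (0.0343).

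Markers of other cells that a splenic sort could hold differed in part. Of 16 macrophage markers, 7 were called higher in pDC, Adgre1 lower (-1.19, a call lost without cDC replicate 2 at an adjusted p of 0.124 and without pDC replicate 2 at 0.107) and 8 were not called (9 and 2 when adjusted over the list alone), with the iron exporter gene Slc40a1 (3.73), Cd5l (3.31) and the complement genes C1qc (3.08) and C1qa (2.68) the most raised. The list passed camera (median 0.69, adjusted p = 0.00675; adjusted p = 0.54 with an estimated correlation). C1qa was not called without cDC replicate 2 (adjusted p = 0.126) or pDC replicate 1 (adjusted p = 0.0946), nor was Cd5l without cDC replicate 2 (adjusted p = 0.0662). Without cDC replicate 2 the higher macrophage markers numbered 4, and Fcgr1 (-0.97, adjusted p = 0.519 with all arrays) was called lower (-2.06, adjusted p = 0.0257). Of 12 monocyte markers Ccr2 was higher (1.55), 3 were lower, with Treml4 at -5.27, and 8 were not called (2 and 3 when adjusted over the list alone, camera adjusted p = 0.439). Ccr2 was not called without cDC replicate 1 (adjusted p = 0.0559) or cDC replicate 2 (adjusted p = 0.0502). Without pDC replicate 1 the lower ones numbered 1. Of 12 NK cell markers Klrd1 was higher (1.17), 3 were lower and 8 were not called, also when adjusted over the list alone (camera adjusted p = 0.229, and 0.0384 without cDC replicate 2). Klrd1 was not called without pDC replicate 1 (adjusted p = 0.0507) or pDC replicate 2 (adjusted p = 0.0541). The lower NK cell markers numbered 1 without cDC replicate 1 or pDC replicate 1, and without pDC replicate 2 none was called by limma. Of 14 stromal and endothelial markers 3 were higher, with Cdh5 at 3.81, Vwf was lower (-3.58) and 10 were not called, also when adjusted over the list alone (camera adjusted p = 0.807), and the median (-0.06) was negative where the mean (0.23) and the test were positive. That median was -0.12 without cDC replicate 2, -0.0993 without pDC replicate 2, -0.0223 without pDC replicate 1 and 0.00694 without cDC replicate 1. For Cdh5, 1 of 2 probe sets was called, and the other differed by 0.47. Without pDC replicate 1, 1 stromal or endothelial marker was higher. Of 10 erythroid markers Tfrc (2.71) and Ermap (1.59) were higher and 8 were not called, also when adjusted over the list alone (camera adjusted p = 0.515), and the call of Ermap was lost without cDC replicate 1, cDC replicate 2 or pDC replicate 1 (adjusted p = 0.0901, 0.184 and 0.0889).

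No member of the remaining lists of granulocytes, mast cells or platelets was called by limma on its brightest probe set. Among 16 neutrophil and granulocyte precursor markers 2 had an unadjusted p under 0.05, among 9 mast cell and basophil markers 2 and among 8 megakaryocyte and platelet markers 0, and the counts adjusted over the list alone were 0 in each (camera adjusted p = 0.542, 0.252 and 0.912). Of the 2 Hdc probe sets the dimmer was called lower (-1.59), as was the mean of both (-1.06, adjusted p = 0.0226). Tpsb2 was called lower without cDC replicate 2 (-0.88, adjusted p = 0.042) and Clec1b higher without pDC replicate 2 (1.04, adjusted p = 0.0406). Of 17 lung epithelium markers Abca3 was called lower (-0.66) and 16 were not called (0 when adjusted over the list alone, camera adjusted p = 0.304). Its call was lost when any array was left out (adjusted p from 0.0662 without cDC replicate 1 to 0.166 without pDC replicate 2). The surfactant gene Sftpc lay at 3.8 on the log2 scale in both cell types, against array medians of 3.69 to 3.77. Abca3 (8.28 in cDC and 7.61 in pDC), Hopx (6.87 and 6.42) and Epcam (6.25 and 6.10) lay above those medians, and levels of different probe sets give no ranking of their transcripts.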

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

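The floor at each array's median was chosen after seeing the data, and the other alternatives were planned. The higher call of Dusp9 in pDC held under every alternative run, with log2 differences from 2.23 without pDC replicate 1 to 3.81 for the mean of its probe sets and adjusted p in limma from 9.7e-05 with a robust trend to 0.0142 with the floor. No called result changed direction under any alternative run. Probe sets called in both the reported fit and an alternative numbered from 3608 without cDC replicate 1 to 6004 with array weights, and each had the same direction in both. Quantile normalisation, median centring, the filter on dim probe sets, either trend and array weights left the counts of higher and lower probe sets within 1.5 times the reported ones. The share of calls that were higher in pDC stayed between 52.5% and 58.7% over the scalings.

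Stricter thresholds lowered the counts by construction, from 3364 higher and 2649 lower in pDC. With at least a 2-fold change added 2175 were higher. At an adjusted p under 0.01, 1641 were higher and 1374 lower, and testing against a 2-fold change with treat gave 774 and 748. Leaving out each array in turn, with the lone array of a cell type assumed to vary like the other type, gave 1972 (without cDC replicate 1) to 2546 (without pDC replicate 2) higher and 1694 (without pDC replicate 2) to 1975 (without cDC replicate 2) lower, with fewer samples in each fit. Of the 155 named genes 100 to 102 were then called, against 120. The floor left 2300 higher, 1820 lower and 91 named genes called, and the largest loss of difference among named genes was that of Il12b, which fell by 0.826 on the log2 scale.

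Of the 12 gene lists past the threshold, 0 passed in camera with an estimated correlation, where 7 of 35 had an unadjusted p under 0.05, against 17 past the threshold in fry. Simulated lists of independent genes raised 2-fold passed in 0 of 5 cases that way, so this count says little about stability. Without a given array 12 or 13 lists passed, with the mean of a gene's probe sets 12, and with the floor 11, while fry passed 7 lists that camera did not. The interferon-stimulated genes did not pass without cDC replicate 1 (adjusted p = 0.0791), with the floor (0.139) or in fry (0.345), nor did the macrophage markers in fry (0.0549), and the cause was not tested. After the filter on dim probe sets 33 lists could still be tested and 11 passed. The robust trend was not run for lists, since camera has no such setting. With the replicate number as a block, 4410 probe sets were higher and 3508 lower, 126 named genes were called (Itgax, Mmp9, Dusp28, Ndufs4, Ndufv2 and Rps15 in addition, at adjusted p of 0.0254, 0.045, 0.0224, 0.0235, 0.0167 and 0.0443) and Dusp9 had an adjusted p of 0.00028. The deviations of cDC replicate 1 and pDC replicate 1 from their group means correlated at 0.208 across probe sets and at 0.268 over those brighter than the median. The labels name no animal or day shared by samples of equal number. Whether such samples share a step stays open, and the reported fit does not account for one. Signal over background limits what the dim end can show. The floor ended the calls of 29 named genes, bright ones such as Irf8 (log2 0.66 in both fits) among them. Of the 29, 24 kept their log2 difference, so the floor did not change their own values. Their calls were lost through the prior or the adjustment, which all probe sets share, and these were not told apart.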

Other observations

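The tests of explanations reported here were chosen after the results they bear on were seen. The genes in this paragraph were also chosen after their values were seen. Beyond the genes already named, those next in size of difference and higher in pDC included Upb1 (log2 7.09), which encodes an enzyme of pyrimidine breakdown, and Cox6a2 (6.36), which encodes a muscle isoform of a cytochrome oxidase subunit, both in the pDC marker list. Pgam2 (6.76), Chdh (6.69), which encodes choline dehydrogenase, Havcr1 (7.09), Mctp2 (6.81), Slc49a4 (6.70), Capg (6.54) and the metalloprotease inhibitor gene Timp2 (6.24) were of like size, with adjusted p in limma from 5.14e-05 for Upb1 to 0.000237 for Cox6a2. Sh3bgr was higher by 6.82 on its brightest probe set, but 1 of its 3 probe sets was called, and 1 of 2 was for Slc49a4 (the other at 0.23), 4 of 6 for Timp2 and 2 of 3 for Pclaf. The other probe set of Capg, also called, differed by 0.72. In the other direction, the metalloprotease gene Adam8 (-6.02), Asb2 (-5.99), Cbr3 (-5.74), Fgl2 (-5.74), Rasgrp3 (-5.71) and Sult1a1 (-5.60) were lower in pDC, as were Pclaf (-5.96) and Cdca8 (-5.63), which were outside the cell cycle list.

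Xist lay between 11.4 and 12.4 on the log2 scale on all 4 arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty lay between 2.68 and 3.35. Xist was called higher in pDC (0.81, adjusted p in limma 0.0190), a call lost without cDC replicate 1 (0.0908), pDC replicate 1 (0.0902) or pDC replicate 2 (0.0552). The ratio of the 3' to the 5' control probe set of Gapdh was 4.87 and 5.35 on the cDC arrays and 5.03 and 5.89 on the pDC arrays. That of beta-actin was 1.40, 1.36, 1.60 and 1.56. The polyadenylated spike controls averaged 10.1 on cDC replicate 1 and 9.14 to 9.46 on the other arrays on the log2 scale.

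Interferon-stimulated genes were higher on cDC replicate 1 than on cDC replicate 2 in 28 of 29 cases, by a median of 1.11 (95% interval over the genes 0.65 to 1.31). These genes vary together (estimated correlation 0.721), and an interval over genes does not measure the spread between arrays. A step that raised these genes on both arrays numbered 1 is argued against by the pDC arrays. Their median difference was -0.0502 (95% interval over the genes -0.23 to 0.14). A shared step to which only cDC responded cannot be weighed in this way. Deviations from the group means correlated at 0.208 between cDC replicate 1 and pDC replicate 1 across probe sets, so other shared shifts stay open. Among 10000 random lists of matched brightness 0 had a median as high, the highest being 0.275. The difference was thus larger than in other genes of like brightness. A change of scale across the array cannot be weighed in this way. The values were already normalised, and all genes had a median difference of 0.0124 between the cDC arrays. Handling of cDC replicate 1 alone stays open and was not tested, and its polyadenylated spike controls also stood apart (10.1 against 9.14 to 9.46). A difference between the mice or cells behind these samples may remain as a hypothesis, but the labels give no group that would separate them and no biological explanation was tested.

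Some macrophage genes were higher on the pDC arrays, with 7 of 16 measured markers called higher (4 without cDC replicate 2, 5 without pDC replicate 1, 6 without cDC replicate 1), and 1 of the 16 is also in another list. RNA of macrophages carried through the PDCA-1 beads is a candidate source, although the later stain for CD11c and B220 should remove most such cells. Cd68, at a mean intensity of 3692 in pDC against 856 in cDC, Cd5l (325 against 31.3) and C1qc (128 in pDC) would go with it. C1qa, Cd5l, Vcam1 and Slc40a1 were higher on replicate 1 than on replicate 2 in both sorts, by 1.26, 1.01, 1.48 and 0.93 on the cDC arrays and 1.28, 1.33, 1.40 and 0.57 on the pDC arrays. Shifts found in both sorts do not speak for the PDCA-1 beads. Adgre1 moved oppositely (-0.49 in cDC and 0.49 in pDC), and 11 of the 16 markers were higher on replicate 1 in each sort. Between the sorts Vcam1 was not called (2.11, adjusted p in limma 0.104). Adgre1, which encodes the F4/80 antigen, was lower in pDC (-1.19, a call lost without cDC replicate 2 at an adjusted p in limma of 0.124 and without pDC replicate 2 at 0.107), Fcgr1 was called lower only without cDC replicate 2 among the fits that left out an array (-2.06, adjusted p 0.0257), Hmox1 was not called (-0.09), Cd5l lost its call without cDC replicate 2 (0.0662), and Cd68 was lower on replicate 1 in both sorts (-0.59 in cDC and -0.27 in pDC). Carried-over RNA cannot be told apart from expression in pDC themselves, because the markers went both ways between the sorts and between replicates and no array holds macrophages alone.

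Cell cycle genes were lower on the pDC arrays in 28 of 29 cases, by a median of -3.22. Granulocyte or erythroid precursors in the CD11c sort are argued against as the source by their markers. Those of granulocytes had a median difference of -0.0654 (95% interval over the genes -0.18 to 0.05) at a median log2 level of 3.64 in cDC. That median was -0.0869 to -0.0258 when an array was left out. The erythroid markers had a median of 0.0168 (-0.20 to 1.59 over the genes) at 3.55, and -0.00682 to 0.104 when an array was left out. No member of either list was called lower with all 4 arrays in the reported fit. Intervals over genes treat them as independent and do not measure the spread between arrays. Monocyte precursors were not weighed in this way. Of 12 monocyte markers 3 were called lower, with Treml4 at -5.27, 1 was called higher and 8 were not called. Among 10000 random lists of matched brightness 0 had a median as low, the lowest being -0.54, so other genes of like brightness differed less. This comparison cannot weigh a change of scale. The values were already normalised, and all genes had a median difference of -0.0245. Dividing dendritic cell precursors within the CD11c gate stay open, as Kit, which precursors express, was lower in pDC (-4.01 on its brightest probe set and -0.96 on the other), but a call of Kit alone does not separate them from dividing cDC. A higher share of dividing cells among cDC than among pDC after Flt3L might be a biological hypothesis, which these arrays do not test further.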
